A study of Caenorhabditis elegans with 2 samples.

How the data were processed

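ChIP-seq peaks were measured in whole L2 larvae of *C. elegans* in 2 biological replicates, with DNA fragments of 150 to 350 bp per the labels. The data are 8 deposited peak lists in 2 genome builds (ce11 and ce10): for each build, a relaxed list of peaks and background per replicate and on the pooled replicates, and the optimal set chosen by irreproducible discovery rate (IDR), per the labels. The peak caller, aligner, IDR threshold, control treatment and sequencing depth are not given in the sources used here. The deposited signal value of each peak is the authors' own, its scaling is not stated, and it was used to rank, filter and describe peaks within a list, for rank correlation, and to sum peaks per gene region within a list. Ratios of such sums to the median over genes depend on that scaling and on the peaks included. The deposited −log10 q-value of each peak reaches a ceiling shared by many peaks (1510 IDR peaks in ce11) and was not used for ranking. The IDR files carry no IDR values.

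All peaks lay on the 6 nuclear chromosomes and none extended past a WBcel235 (ce11) chromosome end. All 2103 ce11 IDR peaks were identical to pooled peaks, and they were the 2103 pooled peaks of highest signal. The ce11 relaxed lists hold 30000 peaks for each replicate and 28651 for the pool. Most peaks have a fixed width, 350 bp in replicate 1, 380 bp in replicate 2 and 376 bp in the pool. At a −log10 q-value of at least 2 the deposited lists hold 8928 peaks in replicate 1, 4755 in replicate 2 and 4869 in the pool. These numbers do not give depth, so precision is limited to counting error over peaks and the spread of 2 replicates.

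Genes, transcripts and sequence came from WBcel235 with Ensembl release 115, and gene products from RefSeq. Target region signal was the sum over the 5000 highest-signal peaks with summits within 15 kb of the middle of each of 19973 protein-coding genes. Replicate lists were cut to 2103 peaks and compared by overlap of at least 1 bp. Chance overlap and location came from 1000 circular shifts within chromosomes (100 for the annotation classes and for the other overlap rules). Annotation classes were assigned in the order promoter window, 5' UTR, coding exon, 3' UTR, intron, non-coding gene and intergenic. Motifs were searched on both strands within 50 bp of the summit and in equal windows 500 bp to either side. The exact McNemar test used 1 flank per peak, drawn with a fixed seed, and percentages use the mean of both flanks. All 2080 6-mers, with reverse complements merged, were tested in the same way. Gene lists were compared with all other protein-coding genes by Fisher's exact test, and tRNA genes with other non-coding genes, leaving out piRNA genes and pseudogenes. Of 18 heterochronic genes asked for, 13 are protein-coding genes of the annotation, so that list is incomplete, and members of other lists were all matched. Of the promoter peaks, 270 (24.5%) lay in the windows of 2 or more genes and counted for each.

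Named genes followed a rule set before the data were examined: mdl-1 and ZK337.2, genes whose nearest start lies within the promoter window of the 20 highest-signal IDR peaks also present in both top lists, up to 4 bound members per list by signal, and all Myc and Mad network members. Peaks named outside this rule are said to be so. Means with SD over n = 2 come from the separate top lists. The replicates form 1 group, so groups of samples could not be compared, and p-values concern positions and genes. The labels call the replicates biological. Alternatives covered the build, overlap rule, peak number, windows, flanks, gene assignment, background and each replicate alone.

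The methods were tested on simulated data. With CACGTG planted at 13.6% of 2103 random windows, the summit share rose by 13.5 percentage points, and CACGTG ranked 1 by p among 2080 6-mers. With nothing planted, 0 6-mers were called. Random windows and their flanks have no systematic base difference, unlike those of the data, so calls due to base composition were not simulated. In simulated gene lists over 19973 genes, 100% of enriched and 0.4% of unchanged lists were called. These lists were all of the same size, with a strong planted excess and genes drawn independently. Shorter lists, weaker excesses and genes that share a peak were not simulated, so these rates need not hold for the lists tested here. With 69.2% of 2103 peaks made shared, 69.5% were found shared. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.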

Results

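Chromatin from whole L2 larvae of *Caenorhabditis elegans* was immunoprecipitated through an eGFP tag and sequenced in 2 biological replicates of 1 group. The strain, OP355, carries an integrated transgene (wgIs355) with a tagged transcription factor gene. The labels disagree on the factor: the source and antibody fields name mdl-1, which encodes a Mad-like basic helix-loop-helix protein, and the description names ZK337.2, listed as klu-1 in the reference annotation. No other condition was part of the series, and the control library that the labels mention was not used here. The comparisons are therefore between the replicates, between peak positions and the rest of the genome, and between the loci of the labelled targets. Read depth is unknown for both replicates, and intervals given below cover counting error only. Peaks and genes are not independent replicates, so their tests describe these peak lists.

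The tagged gene came first, because it checks the labels. The gene mdl-1 (WBGene00003163, X, 6742351 to 6743899, plus strand, ce11) lay in the region with the highest summed peak signal of all 19973 protein-coding genes in both replicates. Among the 5000 highest-signal peaks of each replicate, 19 in replicate 1 and 25 in replicate 2 had a summit within 15 kb of the middle of mdl-1, and their signal summed to 1789 and 3316. These sums were 156 and 187 times the median over genes, a ratio that depends on the cut, since the median gene had 1 such peak. It was 41.9 and 47 with all relaxed peaks, and 67.4 and 78.9 with summits within 25 kb. At 25 kb, 2 genes had a higher sum than mdl-1 in replicate 1. Both were its neighbours, and their windows held the same peaks and a further peak with a signal of 10.8. ZK337.2 (WBGene00013970, I, 14975419 to 14980596, plus strand) had 0 peaks in replicate 1 and 1 peak in replicate 2, with percentiles of 0 and 68.3.

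The IDR set is the authors' optimal list by irreproducible discovery rate, and not every peak in it has a counterpart in each replicate. Its highest-signal peak lay at X, 6741988 to 6742502, with its summit 97 bp upstream of the mdl-1 start and a signal of 986. It ranked first in each replicate. Its window held CACGTG at 6742226 to 6742231, in the sequence CGAGGCGCACGTGCATACAC on the plus strand. The peak ranked second, at X, 6737387 to 6738013, was intergenic and held CACGTG in the sequence TGGGATGCACGTGCGCCAGC. The peaks ranked 7, 9 and 19 lay in an mdl-1 intron, in an intron of the neighbouring gene abts-4 (named outside the naming rule, after its values were seen) and in a non-coding gene 1684 bp downstream of the mdl-1 start. In all, 19 IDR peaks had summits within 20 kb of mdl-1, against at most 13 at any gene over 40 kb away and a median of 0 over genes. Within 20 kb of ZK337.2 there was 1 IDR peak, with a signal of 40.2. These percentiles are descriptions with no test, and signal values are compared only within a list.

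**Figure D1:**
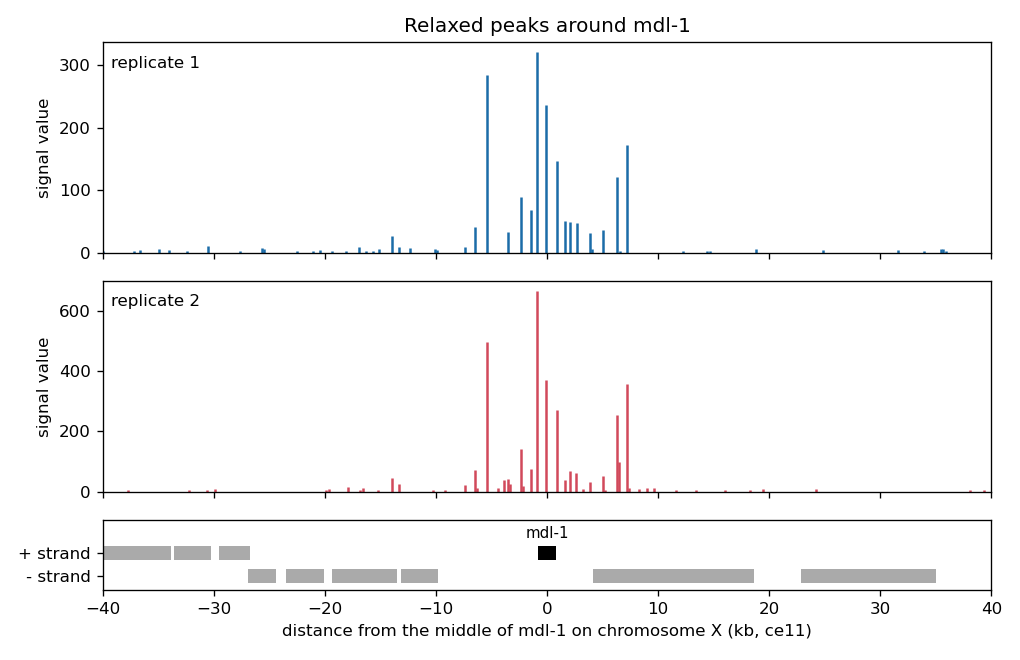
Relaxed peaks within 40 kb of the middle of mdl-1 on chromosome X (ce11). Each line is 1 peak, its height the signal value (linear axis) in replicate 1 (top) or replicate 2 (middle), and the bars at the bottom are protein-coding genes by strand, with mdl-1 in black; the highest lines reach 320 and 665 just upstream of mdl-1.

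The IDR set held 2103 peaks in ce11, with signal values from 32.5 to 986 and a median of 51.5. The replicates were compared through their own 2103 highest-signal peaks. Of the replicate 1 peaks, 1458 (69.3%, exact 95% binomial interval 67.3 to 71.3) overlapped a replicate 2 peak by at least 1 bp. Their summits lay a median of 29 bp apart, and signal values at shared peaks had a Spearman correlation of 0.724 across peaks. Across the 2092 IDR peaks that overlap a relaxed peak in each replicate, the correlation was lower, at 0.637. The shared share was 99.4% for replicate 1 ranks 1 to 500, 86% for ranks 501 to 1000, 60.2% for ranks 1001 to 1500 and 38.1% for ranks 1501 to 2103. Shifting the replicate 2 peaks along each chromosome gave a mean of 1.49% and at most 2.66% (one-sided circular-shift permutation test, p = 0.000999, the smallest that 1000 shifts can give). The top lists of replicates 1 and 2 contained 80.3% and 86.9% of the IDR peaks, and their relaxed lists contained 99.5% and 99.95%.

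**Figure D2:**
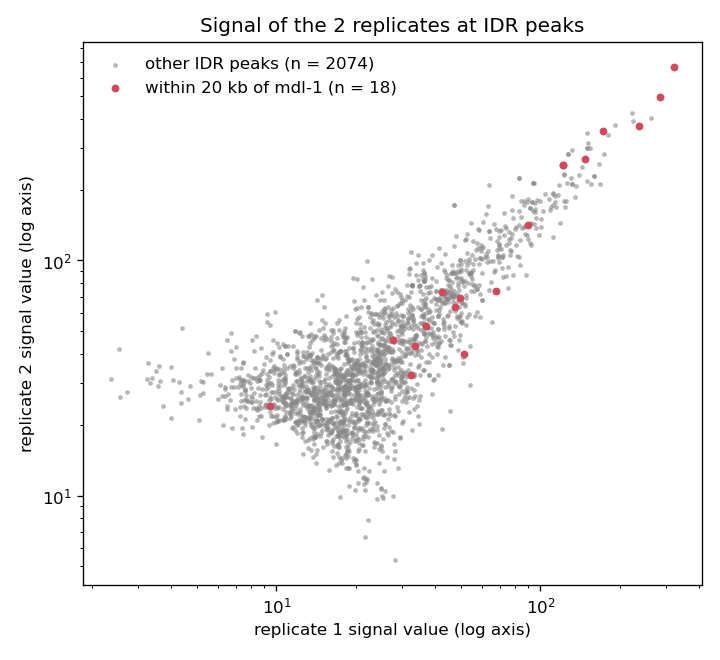
Signal value of replicate 1 against replicate 2 (both log axes) at the IDR peaks that overlap a relaxed peak in each replicate, with 1 point per peak. The peaks within 20 kb of mdl-1 (red) include the points highest on both axes, at 320 and 665.

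Summits lay mostly upstream of genes and avoided coding sequence. Of the 2103 IDR summits, 1102 (52.4%) fell from 1000 bp upstream to 200 bp downstream of a protein-coding start, here called the promoter window, against 25.7% ± 0.990 (SD over 1000 shifts) by chance, a ratio of 2.04. Coding exons held 15 summits (0.713%), against 18.8% for shifted positions. Introns held 16.9% against 27.2%, and intergenic sequence held 24.9% against 22.3%. The median summit lay 271 bp upstream of the nearest start, and 76.3% of summits were upstream of it. The top lists of the replicates had 51.2% ± 0.874 (SD, n = 2) of summits in promoter windows and 0.737% ± 0.0336 (SD, n = 2) in coding exons. The promoter share passed a one-sided circular-shift permutation test (p = 0.000999, the smallest that 1000 shifts can give).

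**Figure D3:**
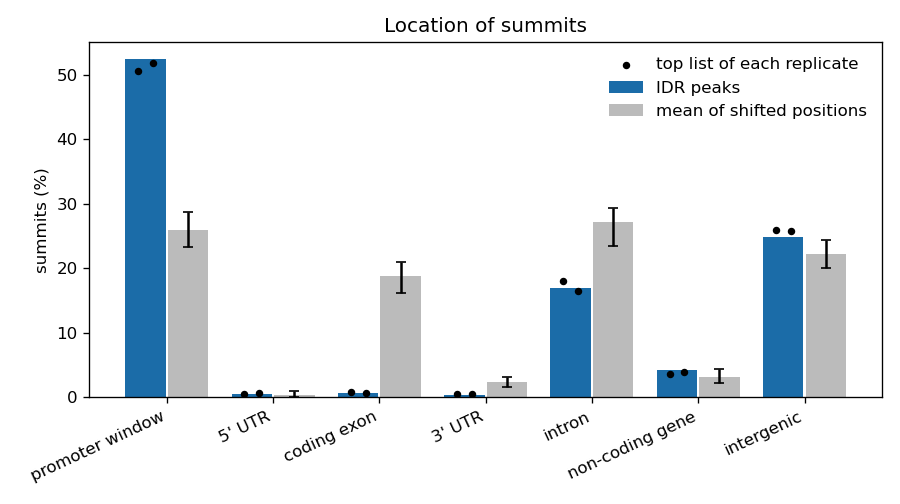
Percent of summits per annotation class for the 2103 IDR peaks (blue), the mean of 100 sets of shifted positions (grey, with bars for their lowest and highest values) and the top list of each replicate (points). Promoter windows hold 52.4% of IDR summits, and coding exons hold 0.713%.

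Among the 20 highest-signal peaks, each of which overlapped a top peak of both replicates, 5 lay in promoter windows. Their genes were mdl-1, tasp-1 (a TASPase homolog, 51 bp upstream, signal 615), epn-1 (an ENTH domain protein, 442 bp upstream, signal 607), tos-1 (105 bp upstream, signal 456) and iff-2 (eukaryotic translation initiation factor 5A, 84 bp upstream, signal 421). The rest lay outside these windows, some of them close to a start, such as the peak 690 bp downstream of the mdl-1 start. The genes in the rest of this paragraph are outside the naming rule and were named after their values were seen. The highest-signal peak not near mdl-1, at III, 12583503 to 12583852, was intergenic, 8286 bp upstream of aakg-1, with a signal of 663 and CACGTG in the sequence AGACAGGCACGTGTGGTCCA. Other peaks lay 1039 bp upstream of mtm-3 (signal 647), 2045 bp upstream of hif-1 (hypoxia-inducible factor, signal 448) and 1754 bp upstream of egl-9 (its prolyl hydroxylase, signal 429). A separate, weaker peak lay 69 bp upstream of the hif-1 start, with a signal of 124.

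Chromosome X carried 514 IDR peaks (24.4%), more than its 13.7% of protein-coding genes and its 17.7% of genome length. Chromosome III was also above its share of genes, at 16.9% against 13.2%. Chromosome V was below it, at 14.9% against 25%. The replicates' top lists had 24.8% ± 0.0336 (SD, n = 2) on X, 15.8% ± 0.740 on III and 15.1% ± 1.18 on V. Over 6 chromosomes, two-sided exact binomial tests against gene share with Benjamini-Hochberg adjustment gave 7.0e-39 for X, 3.1e-06 for III and 3.9e-29 for V. Chromosome II was below its gene share, at 15.1% against 17.3% (adjusted exact binomial p = 0.0109), but did not differ from its share of length (0.856). Against genome length the adjusted exact binomial values for X, III and V were 3.7e-14, 9.9e-05 and 8.0e-12. Chromosomes IV (15.3% against 17.4%, 0.0145) and I (13.4% against 15%, 0.0456) were below their share of length in this exact binomial test and did not differ from their share of genes (0.203 for each). Without the 40 kb around mdl-1, a setting chosen after seeing the data, the X share was 23.8%.

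CACGTG, the canonical E-box bound by Max and Mad family dimers, lay within 50 bp of 361 IDR summits (17.2%, exact 95% binomial interval 15.6 to 18.8). The flanking windows 500 bp away held it in 2.07%, a ratio of 8.30, and the ratio was 7.89 ± 0.192 (SD, n = 2) in the replicates. The E-box share was 30% at IDR ranks 1 to 300 and 10.6% at ranks 1801 to 2103. It was found at 11 of the 20 highest-signal peaks. Of 17729 CACGTG sites in the nuclear chromosomes, 384 lay within 50 bp of an IDR summit. The GAGA repeat GAGAGA was more frequent than the E-box, at 32.2% of summits against 4.90% of flanks. CTGCGTCT, a sequence frequent at worm promoters, lay at 12.2% of summits against 0.476% of flanks.

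The E-box passed a two-sided exact McNemar test (353 peaks with the site at the summit only and 34 in the flank only, p = 5.1e-68, adjusted 2.0e-67 over 12 motifs). GAGAGA (adjusted exact McNemar p = 7.3e-113) and CTGCGTCT (6.9e-67) passed it as well. The relaxed E-box CAYGTG (27.3% against 5.35%), any E-box CANNTG (48.7% against 31.5%), the GC box GGGCGG (5.28% against 1.76%) and the E2F site TTYSSCGC (5.37% against 2.47%) were also higher at summits. The homeodomain core AATTAA was lower, at 3.42% against 16.4%. The GATA site TGATAA (8.75% against 9.03%), the AP-1 site TGACTCA, the forkhead site GTAAACA and the PHA-4 site TGTTTGCA did not pass. Among all 2080 6-mers, 673 were higher and 514 lower at summits (exact McNemar tests, Benjamini-Hochberg adjusted). By p, in either direction, CACGTG ranked 14 among them. Some 6-mers, such as ACGCAG (8.76) and GACGCA (8.88), had a higher ratio over flanks than its 8.30. Summit windows were 47.6% G or C and flanks 35.5%, a difference that bears on each of these motifs.

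**Figure D4:**
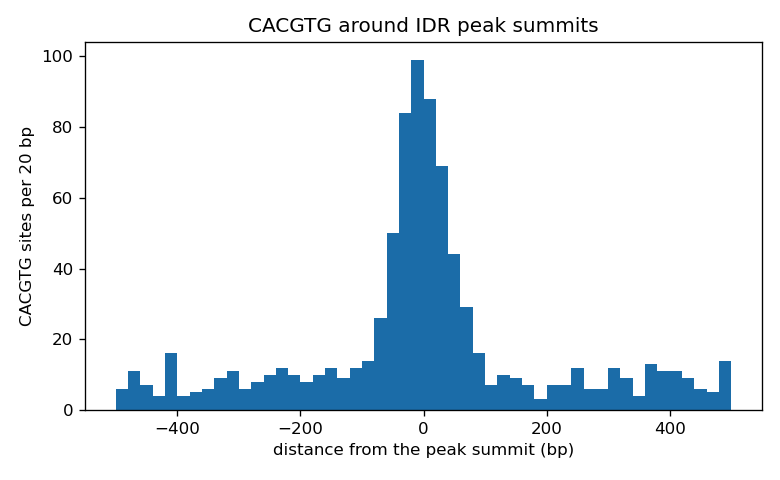
Number of CACGTG sites per 20 bp (vertical axis) by distance from the IDR summit in bp (horizontal axis), over 2103 peaks. The count is highest next to the summit, at 99 and 88 sites, and falls to 7 from 100 to 120 bp on the higher-coordinate side.

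Ribosomal protein, splicing factor, respiratory chain and heat shock genes carried peaks more often than other genes. An IDR summit lay in the promoter window of 1308 protein-coding genes (6.55%), called bound here. Of 78 cytosolic ribosomal protein genes, 41 were bound (52.6%, exact 95% interval 40.9 to 64), against 6.37% of other genes. They included rpl-15 (signal 325), rpl-3 (289), rpl-35 (216) and rps-1 (205), none with an E-box at the summit. The replicates' top lists bound 48.1% ± 2.72 (SD, n = 2) of this list. Splicing factors were bound at 14 of 37, among them snr-4 (94.1), rsp-8 (89.4), snrp-3 (80.1) and rsp-1 (78.9). The mitochondrial respiratory chain had 13 of 40 bound, led by the cytochrome oxidase subunit genes cox-5A (155) and cox-5B (131), then sdha-1 (88.7) and atp-1 (86.4). Heat shock proteins had 13 of 52 bound, with hsp-3 at 121, dnj-13 at 87.9, hsp-1 at 85.6 and dnj-14 at 85.3.

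Two-sided Fisher exact tests, adjusted over 32 lists fixed before the data were examined, gave 5.9e-27 for ribosomal proteins, 3.9e-07 for splicing factors, 5.6e-06 for the respiratory chain and 0.000101 for heat shock proteins. These 4 lists were still higher against the 8369 genes with any pooled relaxed peak in the window (adjusted Fisher exact p = 1.4e-15, 0.000382, 0.00455 and 0.0132). In that background 6 of the 15 called lists that could be tested passed. With each summit given to its nearest start only, 24 of 78 ribosomal protein genes (30.8%) and 8 of 40 respiratory chain genes (20%) were bound (adjusted Fisher exact p = 5.6e-12 and 0.00473), and heat shock proteins did not pass (0.0966). In the 500 highest-signal peaks neither splicing factors (0.354) nor heat shock proteins (0.0613) passed.

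Further lists passed the test against all genes but not against genes with a relaxed peak. In that background their shares were still 1.48 (autophagy and lysosome) to 3.21 (insulin signalling) times those of other genes. Translation factors had 10 of 43 bound (adjusted Fisher exact p = 0.00147, and 0.0874 against genes with a relaxed peak), including iff-2 (421) and the elongation factor genes eef-1A.2 (287), eef-1A.1 (89.1) and eef-2 (71.4). V-ATPase subunits, which acidify lysosomes, had 6 of 20 bound (0.00436 and 0.0838), led by vha-12 (64.2) and vha-8 (50.9). Proteasome subunits had 7 of 33 (0.0129 and 0.343), led by rpn-11 (71.2) and pas-5 (57.6). Insulin signalling had 4 of 12 (0.0146 and 0.0838): the 14-3-3 genes par-5 (117) and ftt-2 (57.9), the kinase gene akt-2 (69.0) and the forkhead factor gene daf-16 (67.7). Autophagy and lysosome genes had 6 of 32 (0.0347 and 0.446), with high-signal peaks at imp-2 (266), lgg-2 (263), epg-7 (195) and atg-9 (129). Cell cycle and replication genes had 5 of 24 (0.0357 and 0.343), among them cdc-6 (53.3), lin-35 (51.2), efl-1 (43.0) and cyb-1 (37.4).

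Without replicate 2, that is in the top list of replicate 1, 4 lists called in the IDR set, other than the Myc and Mad network, did not pass: V-ATPase with 2 of 20 bound (10%, adjusted Fisher exact p = 0.587), cell cycle with 3 of 24 (12.5%, 0.345), collagens with 4 of 175 (2.29%, 0.0626) and cytochrome P450 with 3 of 74 (4.05%, 0.768). Without replicate 1 the proteasome list had 5 of 33 bound (15.2%, 0.0940). At peaks in the top lists of both replicates the calls did not hold for V-ATPase (2 of 20, 10%, adjusted Fisher exact p = 0.371), proteasome (4 of 33, 12.1%, 0.124) and cell cycle genes (3 of 24, 12.5%, 0.168). With nearest starts only, autophagy and lysosome genes (5 of 32, 15.6%, 0.0551) and cell cycle genes (3 of 24, 12.5%, 0.205) did not pass the Fisher exact test. Cell cycle genes did not pass with the window from 2000 bp upstream either (0.0923). In the 500 highest-signal peaks only the ribosomal protein, respiratory chain, chemoreceptor and autophagy and lysosome lists passed, of the 16 called lists. Of the 612 tRNA genes, 93 (15.2%) had an IDR summit in the same window, against 8.27% of 8814 other non-coding genes (adjusted Fisher exact p = 5.5e-07). The tRNA genes W02H3.t1 (113), C28G1.t1 (111), F41D9.t3 (103) and F29C4.t1 (98.8) had the highest signal. The tRNA call did not hold at peaks in the top lists of both replicates (8.17%, adjusted Fisher exact p = 0.0570).

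Of the 6 genes on the fixed list named Myc and Mad network, 3 were bound: mdl-1 (986), hlh-30 (71.4) and mxl-3 (35.1). The gene hlh-30 is also counted on the basic helix-loop-helix list, and its place in the network is that of the list only. Summits were absent from the windows of mml-1, mxl-1 and mxl-2. The list passed with mdl-1 included (adjusted Fisher exact p = 0.0129) and not without the 40 kb around mdl-1 (0.0955), without replicate 2 (0.102), at peaks in both top lists (2 of 6, 33.3%, 0.0633), in the 500 highest-signal peaks (1 of 6, 16.7%, 0.328) or against genes with a relaxed peak (0.0838).

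Chemoreceptor, F-box, collagen and cytochrome P450 genes carried fewer peaks than other genes. Chemoreceptor genes had 8 of 1312 bound (0.610%, against 6.97% of other genes, adjusted Fisher exact p = 1.4e-27), the highest at srh-2 (284) and srh-17 (64.3). F-box genes had 4 of 322 (3.6e-05), namely fbxb-58 (181), fbxa-83 (72.4), fbxb-85 (53.7) and fbxa-90 (43.0). The fbxa-90 peak is also the efl-1 peak named above, 956 bp upstream of fbxa-90 and 183 bp upstream of efl-1. Collagen genes had 2 of 175 (0.00381), col-38 (52.6) and col-185 (36.9). Cytochrome P450 genes had 0 of 74 (exact 95% binomial upper bound 4.86%, adjusted Fisher exact p = 0.0344). That call did not pass with a window from 500 bp upstream to 100 bp downstream (adjusted Fisher exact p = 0.0954), with nearest starts only (0.105), at peaks in both top lists (0.108) or in the 500 highest-signal peaks (1). Against genes with a relaxed peak, chemoreceptors (3.6e-08) and cytochrome P450 genes (0.0338) were lower, and F-box genes (0.0750) and collagens (0.0554) did not pass the adjusted Fisher exact test.

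**Figure D5:**
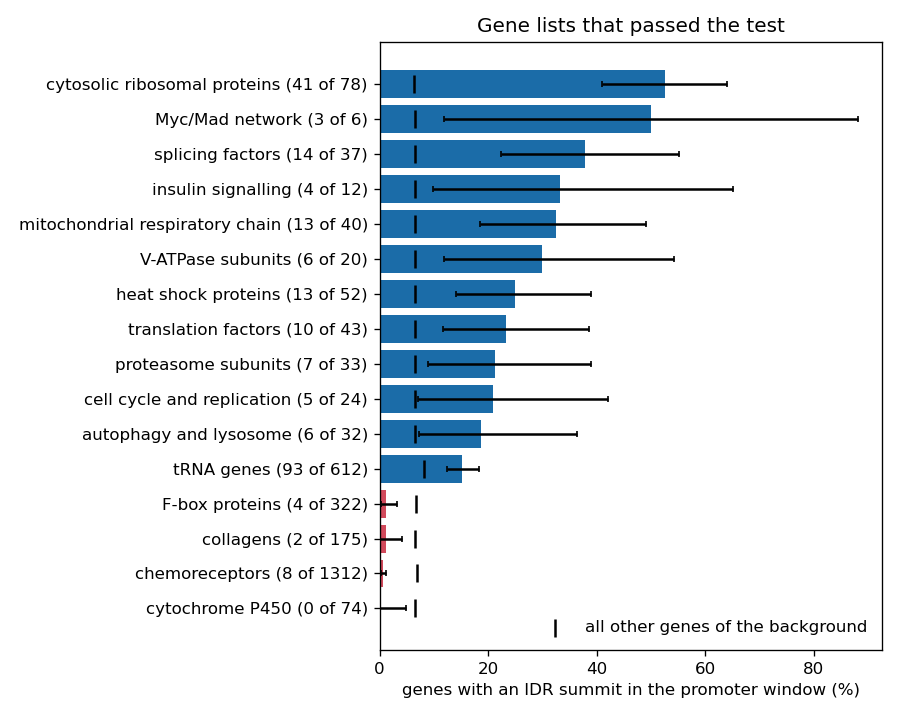
Percent of genes with an IDR summit in the promoter window for the 16 lists that passed the Fisher exact test, with exact 95% binomial intervals (bars), higher lists in blue and lower lists in red. Black ticks mark the percent over all other genes of the background; ribosomal proteins reach 52.6%.

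No difference from other genes passed the test for the remaining 16 lists under the main setting. Marker lists for tissues had few bound genes: intestine 1 of 21 (gst-42, 88.1), hypodermis 0 of 17, body wall muscle 1 of 18 (unc-112, 50.1), pharynx 1 of 13 (peb-1, 41.2), neurons 3 of 28 (egl-21, rab-3 and unc-18) and germline 0 of 19. With lists this short the exact intervals are wide, reaching 19.5% for hypodermis and 17.6% for germline. Among regulators, nuclear hormone receptors had 24 of 269 (nhr-32 at 229, nhr-1 at 166), homeobox factors 2 of 63 (ceh-38 at 215, ceh-20 at 33.8), listed basic helix-loop-helix factors 2 of 25 (hlh-11 at 343, hlh-30) and ztf zinc finger factors 1 of 25 (ztf-7, 205). The basic helix-loop-helix list leaves out mdl-1, a bound gene of that family, so it covers only part of the family. The heterochronic pathway, which times larval cell fates, had 3 of 13 protein-coding members bound: lin-66 (123), lin-28 (77.8) and lin-14 (65.3), with an adjusted Fisher exact p of 0.0869. Transcription machinery had 7 of 50 (0.0813), ribosome biogenesis 4 of 23 (0.101), histones 5 of 72 (his-37 at 137), fatty acid synthesis 2 of 21 (fat-3 and fat-6) and insulin-like peptides 1 of 39 (ins-39, 158). Of the 16, 3 were higher under some alternatives (adjusted Fisher exact tests). Ribosome biogenesis passed with windows from 500 bp (0.0490) and 2000 bp (0.0239) upstream, without replicate 1 (0.0315) and without replicate 2 (0.0328). The heterochronic list passed with the windows from 500 bp (0.0490) and 2000 bp (0.00796) upstream and without replicate 1 (0.0190), and transcription machinery with the window from 2000 bp upstream (0.00796) and without replicate 2 (0.00370).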

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

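CACGTG was also found in pooled peaks that the IDR set leaves out, a signal in data that the comparisons above use mainly as a background and did not search for sequences. At pooled ranks 2104 to 5000 it lay within 50 bp of 7.84% of 2897 summits, against 1.33% of flanking windows, a ratio of 5.90 (two-sided exact McNemar test, p = 3.4e-31). A count of 0 would allow up to 0.104%, from 3 counts. The test was chosen after seeing the data.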

How the results depend on the processing

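The promoter share, the X share, the E-box share, the peak count and the replicate overlap kept their direction and their side of the threshold, or stayed within 1.5 times or the counting interval, under each alternative run. The promoter share ranged with the window from 40.6% to 67.1%, the overlap from 58.2% (top 5000 peaks) to 78.2% (top 500), and the E-box share from 9.65% (within 25 bp) to 25.4% (500 highest-signal peaks). Settings without the 40 kb around mdl-1 were chosen after seeing the data. The signal correlation was 0.755 with summits within 100 bp, 0.805 in the top 500 and 0.678 in the top 5000. The mean mdl-1 percentile was 99.985 with summits within 25 kb, where the main value had no spread between replicates. In the 500 highest-signal peaks 353 6-mers were higher, and 4 gene lists passed, with fewer peaks tested. There the shares fell below other genes for proteasome (0%), V-ATPase (0%) and cell cycle genes (0%) and tRNA genes (1.14%), none past the test. Against genes with a relaxed peak 6 lists passed, and at peaks in both top lists 10 did; the cause was not tested. Of the 16 called lists, 12 did not pass in the 500 highest-signal peaks, 9 of 15 against genes with a relaxed peak, 6 at peaks in both top lists, 4 of 15 with nearest starts only, 5 without replicate 2, and 1 under each other setting. Of the 16 lists not called, 3 passed under some alternatives.

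Leaving out each replicate gave promoter shares of 50.6% to 51.8%, X shares of 24.8% to 24.9%, E-box shares of 14.9% to 15.8%, and 652 to 669 higher 6-mers. The ribosomal protein, respiratory chain and chemoreceptor lists kept their calls under all 9 alternatives. The pooled list equals the IDR set here, so that alternative moved nothing. A stricter IDR value was not run, because the files carry no IDR values. No paired analysis was possible because there is only 1 group. Unknown depth limits any comparison of signal between replicates.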

Other observations

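E-box peaks held GAGAGA less often than other peaks, while GAGAGA and CTGCGTCT shared peaks. These comparisons and the tests below were chosen after the results were seen, with the following exceptions. The signal percentiles at mdl-1 and ZK337.2 and the replicate E-box ratios were set before. The X share of peaks without the 3 sequences was an exception only in part. It left out the 40 kb around mdl-1, a setting chosen after seeing the data. GAGAGA lay at 23.3% of E-box peaks and 34.0% of other peaks (Fisher exact p = 8.3e-05, adjusted over 3 pairs). GAGAGA and CTGCGTCT occurred together at 135 peaks, against 82.4 for independent placement (1.3e-12), and the E-box and CTGCGTCT pair did not pass (0.0924). The reverse complement of CTGCGTCT begins with the 3 bases that end GAGAGA. Overlapping matches in a single longer sequence were not separated, so this excess does not show that separate sites share peaks. None of the 3 sequences lay at 1045 peaks (49.7%). Taking the highest-signal promoter peak of each bound gene, those of ribosomal protein genes held GAGAGA at 3 of 40, against 30.4% of the 987 others (adjusted Fisher exact p = 0.0307 over 27 tests of 9 lists), and the E-box at 2 of 40 (0.329). No other of these 27 passed, among them GAGAGA at 5 of 6 V-ATPase peaks (0.134) and the E-box at 3 of 6 autophagy and lysosome peaks (0.289).

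The bases beside CACGTG differed between sites at summits and the whole genome. GCACGTGC made up 5.73% of the 384 summit sites and 2.35% of genomic sites (exact binomial p = 0.000738, adjusted over 10 flank pairs). ACACGTGC (10.2% against 6.01%, 0.00414) and GCACGTGA (9.64% against 6.62%, 0.0466) were also higher. CCACGTGG (9.38% against 16.9%, 0.000304) and ACACGTGG (12.2% against 19%, 0.0018) were lower. The few sites in flanking windows, not tested, had 2.25% GCACGTGC, 6.74% ACACGTGC, 8.99% GCACGTGA, 19.1% CCACGTGG and 8.99% ACACGTGG, so the last was not lower at summits than there. Of the genomic GCACGTGC sites 5.28% lay at an IDR summit, and of CCACGTGG sites 1.2%.

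The raised signal at mdl-1 is a pattern to weigh because the labels conflict. A transgene was assumed, without a test, to raise peak signal at its own locus. Under that assumption, the percentile of at most 68.3 at ZK337.2 in both replicates argues against a transgene that carries ZK337.2. With the top 1000 peaks its replicate 2 percentile was 83.4. The percentile of at least 99.995 at mdl-1 is what a transgene that carries mdl-1 would give under the same assumption. Binding at usual kinds of site in the native gene stays open: 0 of 19 nearby peaks and 15 of 2084 others (0.720%) lay in coding exons (Fisher exact p = 1), but at so low a share 0 of 19 decides nothing, and extra transgene copies of bound sites would give the same positions. The peaks of native and transgene copies cannot be told apart here. No second group exists to test a biological explanation.

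The E-box share may reflect binding of the precipitated protein to canonical E-boxes, since the lower replicate ratio over flanks was 7.75. The ratio alone cannot decide this, because other sequences also rose at summits. In replicates 1 and 2 the ratio was 6.20 and 6.22 for GAGAGA and 20.1 and 29.5 for CTGCGTCT. Base composition alone is argued against: among 101 other 6-mers of the same bases the highest ratio was 5.56 (ACGCGT) and the median 1.37, against 8.30 for CACGTG. CACGTG was also above the highest of them in replicate 1 (7.75 against 4.96) and replicate 2 (8.02 against 5.17). Whether other E-box proteins hold these sites was not tested, and binding by the protein remains a hypothesis.

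The excess of peaks on X has several technical candidate explanations. The mdl-1 region is argued against as the whole cause, since 23.8% of the other peaks were on X (exact binomial p = 5.2e-35 against 13.7% of genes). A higher density on X of peaks of every strength stays open: all pooled peaks outside the IDR set had 20.3% on X (Fisher exact p = 0.0002 against the IDR set), but the next 2895 below it had 23.3% (0.735), and by pooled rank, also without the 40 kb around mdl-1, the share was 29.4% at 1 to 500, 18.3% to 1000, 24% to 2000, 23.2% to 5000, 21.9% to 10000 and 19.4% beyond (exact 95% interval 18.8 to 19.9, against 17.7% of length). More of the 3 summit sequences on X is argued against by the 26.9% on X among 1034 peaks with none of them (exact binomial p = 2.1e-13 against length). X also held only 13.9% of genomic CACGTG, 16.4% of GAGAGA and 8.96% of CTGCGTCT sites, each below its 17.7% of length. The X share was 22.8% among peaks with CACGTG, 19.3% with GAGAGA and 13.3% with CTGCGTCT. The excess was therefore not shared by all kinds of peak. Open chromatin and control coverage on X were not analysed here and stay open, and no biological explanation was tested.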
